A study of Mus musculus with 8 samples.

How the data were processed

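The series holds droplet-based single-cell RNA sequencing with barcoded antibodies of white blood cells from female C57BL/6J mice that carried a subcutaneous oropharyngeal carcinoma (MOPC cells, a mouse oropharyngeal cancer line). Blood, bone marrow, spleen and tumor gave 1 RNA library and 1 library of antibody tags each. Per the labels' protocols, tumors were digested for 45 min at 37 °C, and each capture was loaded with about 16000 cells. The sort kept living cells that were either Gr1-positive and negative for a set of lymphoid, mast cell and red cell markers, or Gr1-negative and cKit-positive. Cell numbers of the tissues were brought to similar levels before the sort, so shares of cells describe the sorted sample and are no frequencies of the organ.

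The deposited table held raw unique molecular identifier (UMI) counts of 32285 genes, 10 hashtag antibodies and 18 surface antibodies in 20012 cells; per the file headers, the authors made these counts with Cell Ranger 7.0.1, and the submitters' processing notes name the mm10 build. Counts were used as deposited, with no normalization by the authors in the file. The number at the end of each cell barcode was matched to the library of the same number in the sample titles. No source states this tie outright, so the tissue names of cells rest on it. A hashtag was assigned to a cell where its count was at least 20 and at least 3 times that of the next hashtag, which held for 17957 cells (89.7%). 8 hashtags were in use. The labels say that hashtags tell mice and conditions apart and that wild-type and knockout mice were in each tissue, but tie no hashtag to a mouse or genotype. Each hashtag within a tissue was therefore treated as 1 mouse, which is an assumption, no genotype comparison was made, and the genotypes within each group below are unknown.

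All deposited cells were kept. Scrublet, a doublet caller, marked 8 cells (0.04%), which is too few for it to have worked, so cells with several hashtags were left out of the sums per mouse in its place. Doublets within 1 mouse stayed in. Cells were scaled to 10000 counts, log-transformed and clustered in scanpy 1.11.5 on 2000 variable genes, 30 principal components and 15 neighbours with Leiden resolution 1 (igraph 0.11.9), giving 28 clusters. Clusters were named X-like from marker genes fixed before the data were examined; the score that weighs those markers was revised once after a first naming. A name needed at least 3 detected markers. Shares of cells are given with exact Clopper-Pearson 95% intervals, and these, like the limit of 3 counts behind a value of 0, cover counting error only.

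Raw counts were summed per hashtag, tissue and class, with at least 20 cells per sum. For tumor sums the minimum was lowered to 5 cells after the cell numbers were seen. Genes with at least 100 summed UMIs were tested with edgeR's quasi-likelihood test (edgeR 4.0.16, limma 3.58.1, R 4.3.3) in a fit over all tissues of a class, with total UMIs as library sizes and Benjamini-Hochberg adjustment. Every adjusted p of a gene below is from this test, and a gene counts as called under 0.05. Values per gene are log2 fold changes ± standard error (SE), and levels are CPM, the UMIs of a gene scaled to a fixed total of all genes in a sum, as mean ± SD over sums. A fold against a group at 0 is a lower bound, set against 3 counts over that group, and such bounds and ratios cover the cells in the sums unless all cells are named. Each tissue is 1 library, so tissue and library cannot be told apart, and p-values measure only the spread between hashtags.

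Gene lists fixed before the data were examined cover azurophil, specific and gelatinase granules, cell cycle, interferon response, hypoxia and glycolysis, inflammatory cytokines, tumor-associated neutrophil and suppressive genes, trafficking, matrix and angiogenesis, oxidative burst and NET, antigen presentation, lipid and iron handling, unfolded protein and stress, dissociation stress, G-CSF and NAD, apoptosis, stem and progenitor, erythroid, platelet, B cell, T and NK cell, epithelial and tumor cell, and stroma and endothelium genes. They were tested with limma's camera against all other tested genes, with its preset and with an estimated correlation. Named genes come from a rule fixed before the data were examined: the 12 largest and 12 smallest changes among called genes with a mean of at least 10 CPM, without ribosomal, mitochondrial, hemoglobin, immunoglobulin and unnamed genes, and up to 4 members per list with the smallest adjusted p. This rule gave 93 to 103 genes per comparison. The genes printed from them were picked after their values were seen. A plan to print fewer of them, made once it was known which calls other settings end, was dropped, and the counts of other settings cover all 184 genes first picked. Bcl2a1b, Hbb-bs, Hist1h1e, Hist1h4c, C1qc and immunoglobulin genes have close relatives whose reads the counting could split, and Cmss1 overlaps another gene, so their values are uncertain.

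The comparison of mature clusters alone, that of erythroid-like cells and those of surface antibodies were chosen after seeing the data. Surface antibody counts were averaged per hashtag, tissue and class, log2-transformed with 0.5 added and centred on the mean of the 18 antibodies, then compared with two-sided exact permutation tests (scipy 1.17.1) over 108 comparisons, and as an alternative within pairs of equal hashtag number. Hashtag numbers recur in every tissue. Over 2661 genes of mature neutrophil-like sums, deviations from the tissue means correlated between sums of the same number in 24 of 24 pairs at over 0.1 (0.349 to 0.798, median 0.557, own number best in 20; correlations are across genes, which are no independent replicates), so the numbers were taken to pair the sums. Counts with the block had been computed before this check. The values with the hashtag number as a replicate block are given where they change a result.

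Alternatives were TMM factors, DESeq2 1.42.0, other filters, thinning of cells to 1000 UMIs, means of per-cell counts per 10000 (limma with a trend on log2 of the mean plus 0.1, which understates changes of low genes), a stricter hashtag margin, other clusterings and each sum left out in turn. The test was checked on simulated counts with known changes. In the neutrophil-like tumor design it recovered 18% of genes changed 2-fold and 32% of those changed 4-fold, with 2 false calls among 52. The same step recovered 83% and 98% in the neutrophil-like marrow design, and 44% and 78% in the progenitor-like design.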

Results

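Cells of blood, bone marrow, spleen and tumor of mice bearing MOPC tumors were profiled for RNA and surface proteins, and the tissues were compared within each cell class. Blood gave 7763 cells with 34232732 UMIs and bone marrow 5682 with 64092351. Spleen gave 6105 cells with 50111292 UMIs and tumor 462 with 7163843. Median UMIs per cell were 3132 in blood, 7999 in marrow, 3461 in spleen and 8663.5 in tumor. A single hashtag was assigned to 90.7% of blood, 89.6% of marrow, 91.8% of spleen and 47% of tumor cells. Several hashtags were found on 6.99%, 9.93%, 7.5% and 41.3% in the same order.

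Neutrophil-like cells made up 81.8% of the sorted blood cells (95% Clopper-Pearson interval 80.9 to 82.7). They were 66.9% (65.7 to 68.1) of marrow, 63.4% (62.2 to 64.6) of spleen and 23.2% (19.4 to 27.3) of tumor cells, intervals in parentheses. Per hashtag the shares were 85.4% ± 4.05 in blood, 66% ± 3.97 in marrow and 66.7% ± 4.61 in spleen (SD, n = 8 each), and 25.8% ± 11.9 in tumor (n = 5). Clusters named from immature granule genes held 52.9% of the marrow neutrophil-like cells (50.3% ± 5.28 per hashtag, n = 8). The same clusters held 5.79% in spleen (6.08% ± 3.11, n = 8), 0.0787% in blood and 0 of 107 cells in tumor. Monocyte-like or macrophage-like cells were 50.4% (45.8 to 55.1) of all tumor cells and 35.9% ± 5.96 per hashtag (SD, n = 5), against 13.5% in blood, 8.73% in marrow and 15.7% in spleen.

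Progenitor-like cells were 18% of marrow, 2.11% of spleen and 0.0386% of blood cells. None was found among 462 tumor cells, which allows a share of up to 0.649%. Dendritic-like cells were 11.8% of spleen cells, 0.708% in blood, 0.387% in marrow and 0.433% in tumor. The Gr1-positive gate excluded lymphoid markers, yet 10.6% of tumor cells were T- or NK-like and 15.4% B- or plasma-like. Per hashtag these shares were 25% ± 19.7 and 12.6% ± 11.2 (SD, n = 5). The B- or plasma-like cells were of cluster 21, whose cells of all tissues had a median of 9.36% mitochondrial UMIs and 2148 UMIs. Of these 71 tumor cells 65 fell in an unnamed cluster with cell cycle, ribosomal and mitochondrial genes left out, and 35 in a macrophage-like one without low-quality cells. The 49 T- or NK-like tumor cells were named B- or plasma-like with 15 principal components, as were 44 of them without low-quality cells. Erythroid-like cells were 3.03%, 4.45% and 3.54% of blood, marrow and spleen cells, and 0.898% ± 1.3, 4.9% ± 1.51 and 3.66% ± 1.2 per hashtag (SD, n = 8 each). The sort sets these shares, and several depended on the clustering. The progenitor-like share of marrow was 9.12% to 14.6% and that of spleen 0.753% to 3.1% under clusterings other than that without low-quality cells. With Leiden resolution 0.5 neutrophil-like cells were 0.433% and monocyte-like or macrophage-like cells 71.6% of tumor cells. With cell cycle, ribosomal and mitochondrial genes left out the shares were 1.3% and 68.2%.

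**Figure D1:**
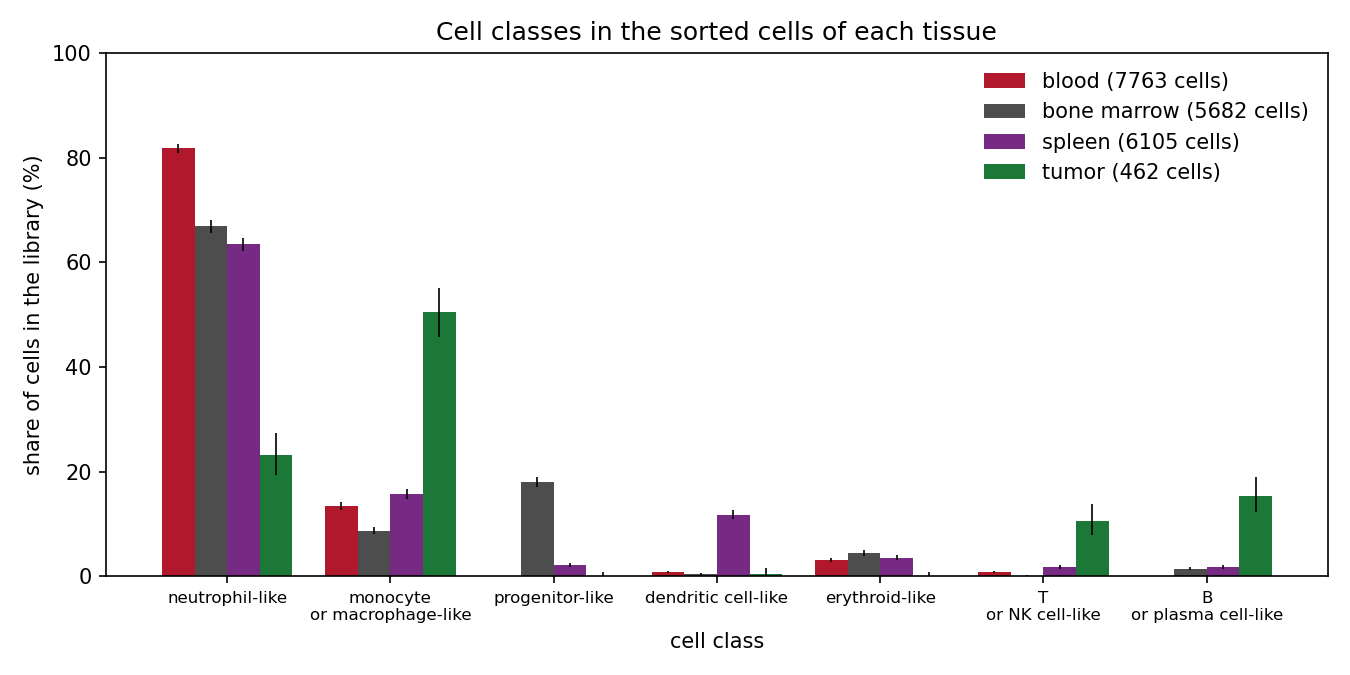
Share of each cell class (% of sorted cells, linear axis) in the 4 tissues. Erythroid-like cells of blood and of marrow were of different clusters. Bars are shares over all cells of a tissue and lines are 95% Clopper-Pearson intervals; neutrophil-like cells fill 81.8% of blood and 23.2% of tumor cells.

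The first comparison asked how neutrophil-like cells of the tumor differ from those of blood. The chemokine gene Cxcl2, whose product draws neutrophils (ENSMUSG00000058427), was at 22572 ± 9243 CPM in tumor (SD, n = 4) and 16 ± 12 in blood (n = 8), a log2 fold change of 10.43 ± 0.43 (SE). The chemokine genes Ccl3 (8.66 ± 0.32) and Ccl4 (8.63 ± 0.45), the cytokine gene Osm (5.72 ± 0.20) and the prostaglandin enzyme gene Ptgs2 (6.04 ± 0.22) rose as well. In the sums Cxcl3 had 1005 UMIs in tumor and 2 in blood, a ratio of 40636 (95% counting interval 11220 to 336005). Il1a had no UMI in all 6350 blood cells of the class and was at least 3262-fold higher in tumor. Of inflammatory genes, 15 of 15 measured members rose (15 adjusted over the list alone), with a median log2 fold change of 5.72. Of hypoxia and glycolysis genes, 14 of 19 measured members rose (14 adjusted over the list alone), including Hilpda (10.30 ± 0.54), Vegfa (4.34 ± 0.33) and Egln3 (3.15 ± 0.29). With cells thinned to 1000 UMIs Egln3 was at 1.88 and not called (edgeR adjusted p = 0.224; over all alternatives 3.22e-23 to 0.224). Of tumor-associated neutrophil and suppressive genes, 12 of 13 measured members rose (12 adjusted over the list alone). Among them were the endotoxin co-receptor gene Cd14 (5.85 ± 0.16), the PD-L1 gene Cd274 (4.42 ± 0.29) and the lectin receptor gene Clec4e (2.13 ± 0.14).

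Of matrix and angiogenesis genes, 6 of 12 measured members rose and 3 fell (7 and 3 adjusted over the list alone), with Thbs1 (7.82 ± 0.42) and Plaur (3.11 ± 0.17) higher. Of lipid and iron handling genes, 4 of 11 measured members rose and 3 fell (4 and 3 adjusted over the list alone). The lipid droplet gene Plin2 (2.81 ± 0.21), the cystine transporter gene Slc7a11 (3.89 ± 0.15) and the ferritin gene Fth1 (2.53 ± 0.11) were higher, and the iron exporter gene Slc40a1 (-3.12 ± 0.22) was lower. Of apoptosis genes, 9 of 11 measured members rose and 1 fell (9 and 1 adjusted over the list alone), with Bcl2a1b (6.19 ± 0.28) and Bcl2l11 (4.34 ± 0.21) higher. Of G-CSF and NAD genes, 6 of 10 measured members rose and 2 fell (7 and 2 adjusted over the list alone), the G-CSF receptor gene Csf3r (-1.19 ± 0.12) being lower. Of antigen presentation genes, 8 of 13 measured members rose and 1 fell (9 and 1 adjusted over the list alone), with Cd80 (3.11 ± 0.16) and Cd74 (2.56 ± 0.49) higher. Cd74 lost its call without tumor hashtag 6 (edgeR adjusted p = 0.0508; over all alternatives 1.7e-10 to 0.0508). Of unfolded protein genes, 5 of 10 measured members rose and 0 fell (5 and 2 adjusted over the list alone). Of dissociation stress genes, which tissue digestion is known to induce, 10 of 13 measured members rose and 1 fell (10 and 1 adjusted over the list alone), with a median of 1.81 and Ier3 (5.47 ± 0.12) and Egr1 (6.55 ± 0.23) higher. The cell cycle inhibitor gene Cdkn1a (10.68 ± 0.25), the nuclear receptor gene Nr4a3 (10.54 ± 0.41), the tissue factor gene F3 (8.63 ± 0.48) and the interferon-inducible gene Gbp2 (4.29 ± 0.28) were also higher.

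Lower in tumor were Anxa1 (-3.30 ± 0.28) and Hmgb2 (-1.96 ± 0.14) and the oxidase subunit gene Cyba (-1.27 ± 0.10). Padi4, which encodes a histone citrullinating enzyme, had 3 tumor UMIs in the sums and lay at 0.0546 (95% counting interval 0.0113 to 0.16) of its blood level. Its fitted log2 fold change of -4.20 was -11.99 without tumor hashtag 6 and -3.60 without tumor hashtag 3. Stfa1 and Hist1h1e had no UMI in the 50 tumor cells of the sums and were each at least 11.5-fold lower there. Over all 107 tumor and 6350 blood cells of the class they had 6 and 2 tumor UMIs and log2 ratios of -3.69 (95% counting interval -5.14 to -2.57) and -5.21 (95% counting interval -8.26 to -3.36), and Padi4 had 11 and -3.44 (95% counting interval -4.45 to -2.60). Stfa1 lost its call without blood hashtag 5 (edgeR adjusted p = 0.0513) or tumor hashtags 3, 4 or 6 (0.128, 0.0518 and 0.237), and with the block (0.091). Its call was also lost with thinning (edgeR adjusted p = 0.349), without low-quality cells (0.0582) and with the stricter hashtag margin (0.448). The same held with 20 cells per tumor sum, which leaves tumor hashtag 6 alone (log2 fold change -11.46). Over all alternatives its adjusted p ran from 8.46e-10 to 0.448. Hist1h1e lost its call with a stricter hashtag margin (edgeR adjusted p = 0.0694; over all alternatives 1.38e-17 to 0.0694). Of azurophil granule genes, 3 of 10 measured members rose (3 adjusted over the list alone). Of specific granule genes, 2 of 12 measured members rose and 3 fell (2 and 3 adjusted over the list alone), and of gelatinase granule genes, 3 of 12 measured members rose and 5 fell (3 and 6 adjusted over the list alone). Of cell cycle genes, 1 of 16 measured members fell (1 adjusted over the list alone), and of interferon response genes, 4 of 17 measured members rose (4 adjusted over the list alone). Of oxidative burst genes, 2 of 11 measured members rose and 4 fell (2 and 4 adjusted over the list alone). Of trafficking genes, 5 of 15 measured members rose and 4 fell (7 and 4 adjusted over the list alone), and the list median of 0.16 was -0.06 with TMM factors. The 1 measured member of the platelet list, Pf4 (3.68 ± 0.52), rose. Pf4 was also among the leading genes of tumor macrophage-like cluster 26, and it was at 2212 CPM over all tumor monocyte-like or macrophage-like cells and 229 over all tumor neutrophil-like cells. Among markers of other cells 1 of 1 stroma gene and 1 of 4 stem cell genes rose, and 2 of 6 erythroid genes fell. None of 2 B cell, 2 T and NK cell and 1 epithelial genes measured was called.

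In all, edgeR called 950 of 9888 genes higher and 1471 lower in tumor. The 4 tumor sums held 17, 5, 22 and 6 cells and 11656 to 121166 UMIs, and the 8 blood sums 1299380 to 3878435 UMIs. Leaving out tumor hashtag 6 lowered the count of lower genes to 815. The highest edgeR adjusted p of the 37 genes named here was 0.0391. Means of per-cell counts gave 876 higher and 5722 lower genes, and thinning 406 and 397. Of called genes 39.2% were higher, 31.6% with TMM factors and 49.9% with DESeq2, and TMM shifted the median of all genes by -0.18. Camera called 13 of 19 lists. With an estimated correlation the calls of these lists were lost, camera adjusted p in parentheses: azurophil granule (0.158), interferon response (0.346) and antigen presentation (0.0866). The block added gelatinase granule and mature neutrophil (0.0563 without and 0.0436 with the block), by camera adjusted p. Median, mean and test differed in sign for azurophil granule, specific granule, gelatinase granule and mature neutrophil, cell cycle, interferon response, oxidative burst and NET and stem and progenitor. Cluster 20 held 105 of the 107 tumor neutrophil-like cells. Its cells had a median of 1.4% mitochondrial UMIs, against 0.0628% to 0.0788% in clusters 0, 1, 2, 4 and 7, which held most of the blood cells. Its leading genes include Cxcl2, Ccl4, Cxcl3, Ccl3, Ier3, Cd14 and Thbs1, so these are not independent of the clustering.

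**Figure D2:**
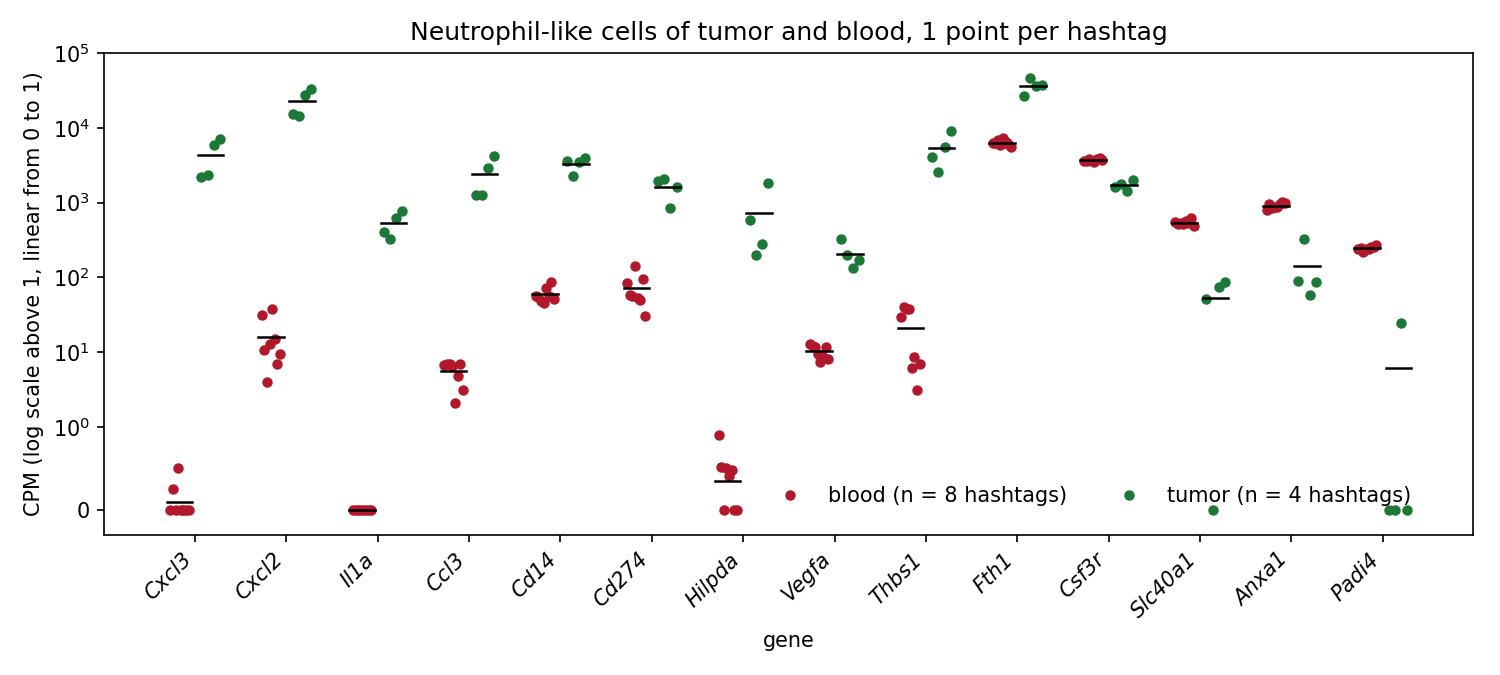
CPM of named genes in neutrophil-like sums of blood (n = 8) and tumor (n = 4), 1 point per hashtag, on an axis that is logarithmic above 1 and linear below; black lines are means. Cxcl2 averages 22572 CPM in tumor and 16 in blood.

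Spleen neutrophil-like cells were compared with those of blood next. Of specific granule genes, 12 of 12 measured members rose (12 adjusted over the list alone), with Camp (8.29 ± 0.60), Ngp (7.08 ± 0.47) and Ltf (6.47 ± 0.42). Also higher in this list were Chil3 (5.21 ± 0.26) and Cybb (3.33 ± 0.24). Of azurophil granule genes, 8 of 10 measured members rose and 1 fell (8 and 1 adjusted over the list alone), and Elane, the neutrophil elastase gene, was at least 990.1-fold higher. Of cell cycle genes, 16 of 16 measured members rose (16 adjusted over the list alone), including Top2a (6.63 ± 0.32). Birc5 and Fcnb had 2 blood UMIs each and ratios of 396 (95% counting interval 109 to 3275) and 1305 (95% counting interval 361 to 10782). The granulocyte transcription factor gene Cebpe (2.73 ± 0.16), the chaperone gene Hsp90aa1 (0.80 ± 0.11) and the MHC class II gene H2-Ab1 (1.94 ± 0.23) were also higher. H2-Ab1 was also a leading gene of dendritic-like cluster 11. Dendritic-like cells were 11.8% of spleen and 0.708% of blood cells, and whether they gave this RNA was not tested. Of dissociation stress genes, 1 of 13 measured members rose and 12 fell (1 and 12 adjusted over the list alone), with Fos (-1.19 ± 0.17) and Jund (-0.78 ± 0.07) lower. The survival gene Mcl1 (-0.73 ± 0.07) and the chemoattractant receptor genes C5ar1 (-0.83 ± 0.08) and Fpr1 (-0.86 ± 0.11) were lower. So were Ccl6 (-0.50 ± 0.10), Fth1 (-0.50 ± 0.09), Defb37 (-2.11 ± 0.17) and Ctla2a (-4.72 ± 0.48). The genes Cmss1 (-1.77 ± 0.08), Cdk8 (-1.52 ± 0.09) and AY036118 (-1.62 ± 0.08) were lower too. Markers of other cells moved with the tissue, and the antibody light chain gene Igkc (7.92 ± 0.22) was higher in spleen and the hemoglobin gene Hbb-bs (-4.70 ± 0.40) lower. Of erythroid genes, 2 of 6 measured members rose and 4 fell (2 and 4 adjusted over the list alone).

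EdgeR called 2501 genes higher and 1299 lower in spleen (n = 8 against 8). Means of per-cell counts gave 185 and 322 in the same order, so that lower genes were the more numerous, and thinning 650 and 327. With these means Camp was at 6.71, Chil3 at 2.91, Top2a at 1.28 and Cebpe at 0.83, all still called. Calls were lost by Hsp90aa1 (0.42), Ccl6 (-0.21) and Fth1 (-0.26), with limma adjusted p of 0.812, 0.627 and 0.163. With thinning Ccl6 (-0.23) and Fth1 (-0.24) lost theirs too (edgeR adjusted p = 0.0801 and 0.062). The highest edgeR adjusted p of the 26 genes named was 0.00012. Camera called 9 of 19 lists. With an estimated correlation it lost, adjusted p in parentheses, azurophil granule (0.0692), gelatinase granule and mature neutrophil (0.0829), lipid and iron handling (0.123) and unfolded protein and stress (0.126). The block added inflammatory cytokine and chemokine (0.0528 without and 0.0383 with the block) by camera adjusted p, and with it stem and progenitor lost its call with an estimated correlation (camera adjusted p = 0.0613). Median, mean and test differed in sign for hypoxia and glycolysis, inflammatory cytokine and chemokine, tumor-associated neutrophil and suppressive, G-CSF and NAD and apoptosis. Immature clusters held 5.79% of these cells in spleen and 0.0787% in blood. Within mature clusters alone, edgeR called 1005 genes higher and 604 lower, and Chil3 was at -0.69 and Cebpe at -0.10 (edgeR adjusted p = 0.185 and 0.719). There Cybb, Ccl6 and Fth1 lost their calls, with log2 values of 0.10 for Cybb, -0.10 for Ccl6 and -0.15 for Fth1 (edgeR adjusted p = 0.841, 0.441 and 0.226). Over all alternatives adjusted p ran for Chil3 from 2.59e-66 to 0.185, Cebpe from 1.63e-46 to 0.719, Cybb from 3.16e-31 to 0.841, Ccl6 from 5.25e-06 to 0.627, Fth1 from 1.95e-06 to 0.226 and Hsp90aa1 from 9.57e-16 to 0.812. Without blood hashtag 1, Camp was at 9.95 and Ngp at 7.96, and without spleen hashtag 8 Ctla2a was at -5.60.

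Bone marrow neutrophil-like cells were compared with those of blood. Of specific granule genes, 12 of 12 measured members rose (12 adjusted over the list alone), and of cell cycle genes, 16 of 16 measured members rose (16 adjusted over the list alone). Examples were Camp (9.91 ± 0.63), Cybb (4.72 ± 0.24), Top2a (7.86 ± 0.30) and Stmn1 (6.97 ± 0.30). The gelatinase list member Mmp8 (1.66 ± 0.13) and Cebpe (4.22 ± 0.16) were higher, Elane was at least 1683-fold higher, and Fcnb had a ratio of 2237 (95% counting interval 619 to 18474). Of inflammatory genes, 1 of 15 measured members rose and 12 fell (1 and 12 adjusted over the list alone), with Il1b (-4.44 ± 0.14) and Ptgs2 (-4.66 ± 0.29) lower. The growth factor gene Csf1 (-4.65 ± 0.21), Cd14 (-3.87 ± 0.18) and Gbp2 (-3.07 ± 0.23) were lower too. Of gelatinase granule and mature neutrophil genes, 3 of 12 measured members rose and 9 fell (3 and 9 adjusted over the list alone), the receptor genes Csf3r (-2.67 ± 0.08) and Cxcr2 (-1.65 ± 0.07) being lower. Of trafficking genes, 3 of 15 measured members rose and 11 fell (3 and 11 adjusted over the list alone), with the integrin gene Itga4 (-3.13 ± 0.12) lower. Of dissociation stress genes, 1 of 13 measured members rose and 12 fell (1 and 12 adjusted over the list alone), with a median of -3.72 and Fos (-4.85 ± 0.21) and Jund (-3.72 ± 0.08). Of unfolded protein genes, 9 of 10 measured members fell (9 adjusted over the list alone), with Atf3 (-6.59 ± 0.27). The genes Mcl1 (-2.68 ± 0.07), Slc40a1 (-2.22 ± 0.08) and Fth1 (-1.98 ± 0.10) also fell.

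In marrow 3293 genes were higher and 4508 lower (edgeR, n = 8 against 8; highest adjusted p of named genes 9.89e-08). With means of per-cell counts there were 1792 and 2502, and with thinning 1053 and 2886. Of called genes 42.2% were higher, 50.4% with TMM and 72.7% with DESeq2, and TMM shifted the median of all genes by 0.21. Camera called 15 of 19 lists. Its calls lost with an estimated correlation, adjusted p in parentheses, were azurophil granule (0.09), inflammatory cytokine and chemokine (0.0546), trafficking (0.0546), oxidative burst and NET (0.0546), antigen presentation (0.193) and apoptosis (0.135). With the block interferon response (0.109 without and 0.00802 with the block) was called by camera adjusted p, and stem and progenitor lost its call with an estimated correlation (camera adjusted p = 0.0715). Signs of median, mean or test differed for hypoxia and glycolysis and matrix and angiogenesis. Camp was at 11.57 without blood hashtag 1 and Stmn1 at 7.73 without blood hashtag 2. Immature clusters held 52.9% of the marrow cells.

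Marrow and blood were also compared within mature clusters, a choice made after seeing the data. Of specific granule genes, 12 of 12 measured members rose (12 adjusted over the list alone), with Camp (7.24 ± 0.14), Ngp (6.37 ± 0.20) and Ltf (4.87 ± 0.20). Higher too were Retnlg (1.94 ± 0.14), Mmp8 (2.23 ± 0.13), Gpr27 (5.26 ± 0.45) and Adpgk (4.5 ± 0.14), and Elane was at least 190.1-fold higher. Of dissociation stress genes, 13 of 13 measured members fell (13 adjusted over the list alone), with a median of -2.07 and Fos (-3.35 ± 0.19) and Jund (-2.19 ± 0.06). Of unfolded protein genes, 10 of 10 measured members fell (10 adjusted over the list alone), with Atf3 (-4.82 ± 0.31). The cytokine gene Il1b (-2.55 ± 0.11) and Itga4 (-1.97 ± 0.12) were lower. Clusters 5 and 14 held most of these cells in marrow, and clusters 0, 1, 2, 4 and 7 most of those in blood. Of 8336 genes 830 were higher and 3345 lower (edgeR, n = 8 against 8; highest adjusted p of named genes 1.37e-11). The split turned on scaling: 19.9% of called genes were higher, 44.5% with TMM and 54.2% with DESeq2, and TMM shifted the median by 0.27. The counts were 354 and 1318 with means of per-cell counts and 444 and 1637 with thinning. Camera called 15 of 18 lists. It lost with an estimated correlation, adjusted p in parentheses, gelatinase granule and mature neutrophil (0.0524), cell cycle (0.0759), inflammatory cytokine and chemokine (0.0995), matrix and angiogenesis (0.0762), antigen presentation (0.272), lipid and iron handling (0.0762), apoptosis (0.161) and erythroid (0.175). Signs differed for hypoxia and glycolysis and matrix and angiogenesis.

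**Figure D3:**
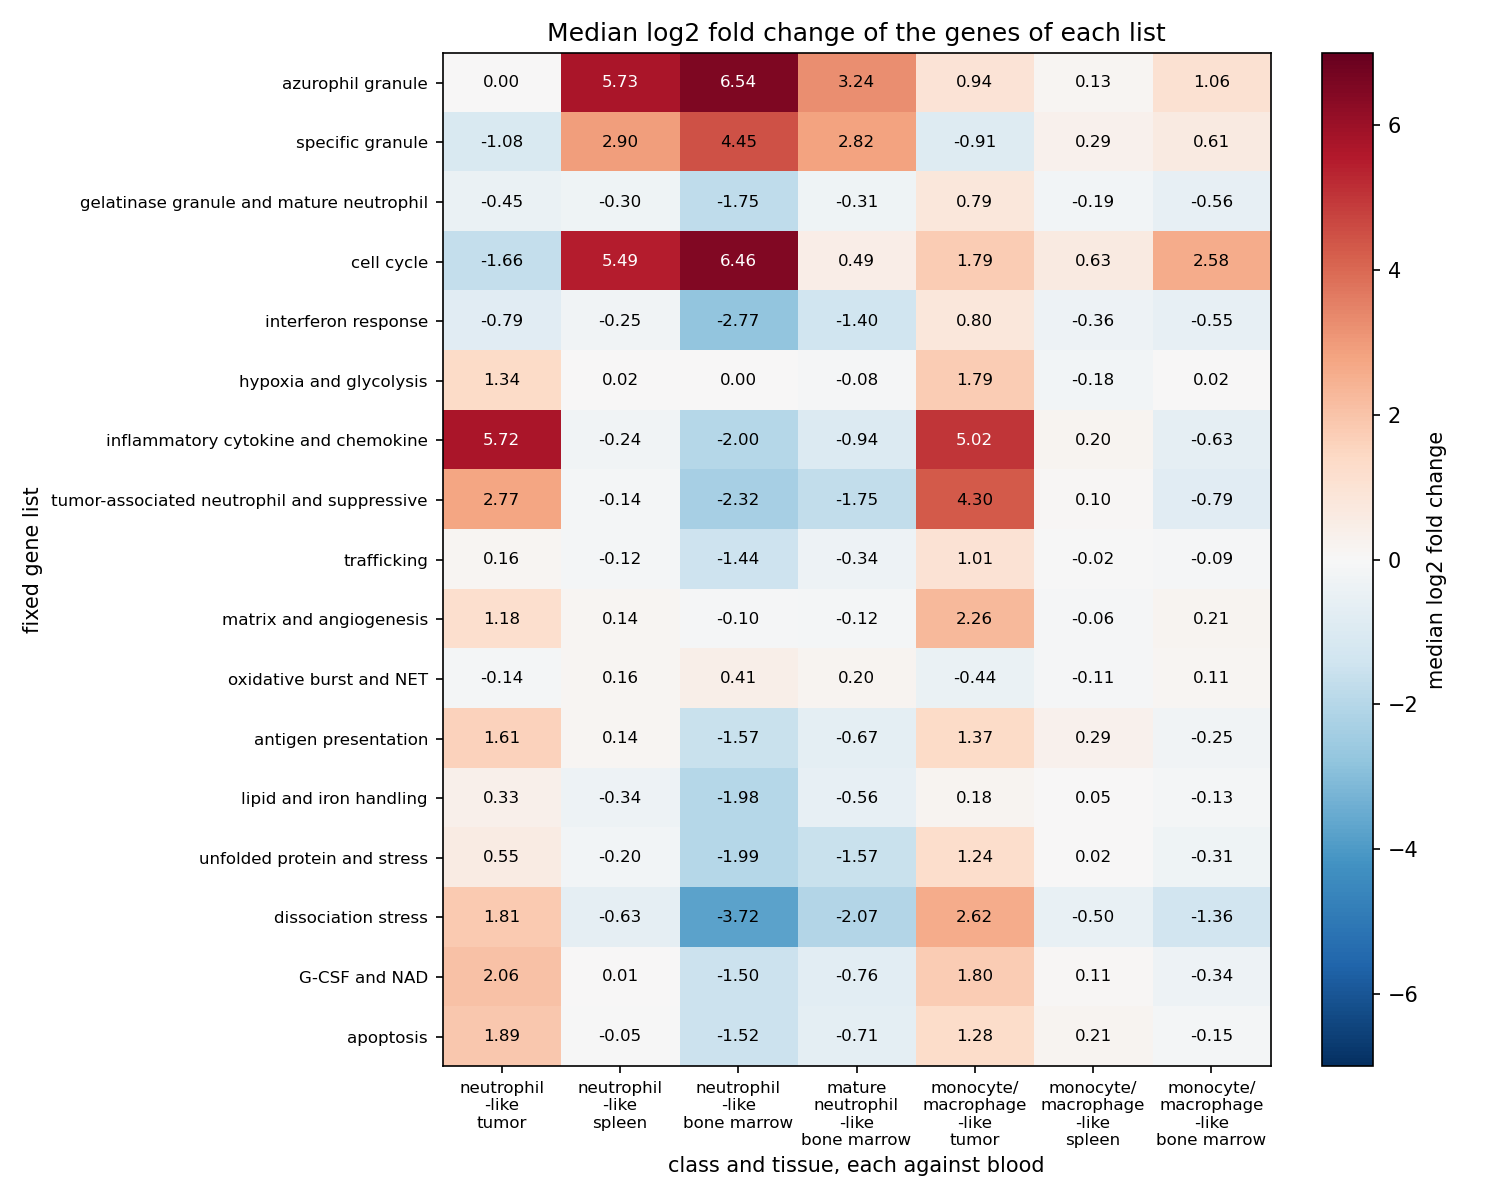
Median log2 fold change (color scale, red higher and blue lower than blood) of 17 gene lists (vertical) in 7 comparisons with blood (horizontal). The inflammatory list lies at 5.72 in tumor neutrophil-like cells and -2.0 in those of marrow.

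Monocyte-like or macrophage-like cells of the tumor were compared with those of blood. Macrophage-like clusters 26 and 27 held 89.7% and 8.15% of the tumor class and no blood cell. Cells of cluster 27 had a median of 363 UMIs. The chemokine genes Ccl8 and Cxcl3 had no UMI in all 1047 blood cells of the class and were at least 2436-fold and 3159.9-fold higher in the sums. The complement gene C1qa had no blood UMI in the sums and 4 in all blood cells, a log2 ratio of 11.11 (95% counting interval 9.75 to 12.98) over all 233 tumor and all blood cells. Also higher were Cxcl2 (12.52 ± 0.51), Spp1 (10.11 ± 0.71) and Pf4 (9.58 ± 0.75), the cholesterol exporter gene Abca1 (5.81 ± 0.31) and Dab2 (9.72 ± 0.36). The arginase gene Arg1 had 3 blood UMIs and a ratio of 2509.5 (95% counting interval 857 to 12186). C1qc and Vegfa had 1 blood UMI each in the sums and ratios of 3796 (95% counting interval 679 to 150165) and 1129 (95% counting interval 200.1 to 44849). Over all cells they had 3 and 13 blood UMIs and log2 ratios of 10.90 (95% counting interval 9.35 to 13.18) and 7.15 (95% counting interval 6.37 to 8.06). Of inflammatory genes, 15 of 15 measured members rose (15 adjusted over the list alone), with a median of 5.02. Of hypoxia genes, 15 of 19 measured members rose and 1 fell (15 and 1 adjusted over the list alone), with Hilpda (5.86 ± 0.21). Of suppressive genes, 10 of 13 measured members rose (10 adjusted over the list alone), and of matrix genes, 9 of 12 measured members rose and 1 fell (9 and 1 adjusted over the list alone), with Thbs1 (6.20 ± 0.32). Of antigen presentation genes, 13 of 15 measured members rose (13 adjusted over the list alone), with the costimulator genes Cd86 (3.58 ± 0.18) and Cd80 (4.46 ± 0.25). Of dissociation stress genes, 13 of 13 measured members rose (13 adjusted over the list alone), with Ier3 (6.34 ± 0.23), and Fth1 (2.21 ± 0.09) was higher. Lower were Cybb (-1.53 ± 0.14), Itga4 (-2.15 ± 0.18) and Hist1h1e (-4.37 ± 0.28). Bmx, with 1 tumor UMI in the sums, and Clec2g, with 2, lay at 0.0144 (95% counting interval 0.000363 to 0.0806) and 0.0248 (95% counting interval 0.00299 to 0.09) of their blood level. Over all cells they had 23 and 11 tumor UMIs and log2 ratios of -4.21 (95% counting interval -4.88 to -3.62) and -4.83 (95% counting interval -5.84 to -3.98). Of T and NK cell genes, 4 of 4 measured members rose (4 adjusted over the list alone), with Cd3d (4.19 ± 0.79), and of erythroid genes, 4 of 4 measured members fell (4 adjusted over the list alone).

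EdgeR called 1946 of 9352 genes higher and 2078 lower in these tumor cells (n = 5 against 8; highest adjusted p of the 23 named genes 4.13e-05). The counts were 1444 and 2790 with means of per-cell counts and 325 and 295 with thinning. Camera called 11 of 21 lists. Lost with an estimated correlation, adjusted p in parentheses, were antigen presentation (0.128), lipid and iron handling (0.068) and erythroid (0.259). The block added specific granule (0.113 without and 0.0412 with the block), oxidative burst and NET (0.0526 without and 0.0307 with the block) and T and NK cell (0.0556 without and 0.042 with the block), by camera adjusted p. Median and mean differed in sign for B cell. Fitted log2 values without tumor hashtag 7 were 8.06 for Pf4, 8.59 for Spp1 and 11.49 for Ccl8, and without blood hashtag 2 14.01 for Cxcl2, 10.76 for Dab2 and 9.74 for Vegfa. C1qc was at 11.49 without blood hashtag 6 and Cd3d at 4.93 without blood hashtag 1. Clec2g was at -8.62 without tumor hashtag 2 and -4.48 without 3. Bmx was at -8.37 without tumor hashtag 6 and -5.16 without 3.

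In monocyte-like cells of the spleen, Adgrl3 (2.26 ± 0.35), Ciita (1.53 ± 0.30) and Cd274 (1.17 ± 0.29) were higher than in blood, as were the adhesion genes Icam1 (0.79 ± 0.18) and Itga4 (0.43 ± 0.13). Ciita encodes the regulator of MHC class II genes. Adgrl3 also led dendritic-like cluster 16 (333 spleen cells), and with Leiden resolution 0.5 a dendritic-like cluster took 35 spleen cells of this class. Whether such cells gave this RNA was not tested. Monocyte-like cluster 8, with a median of 2181.5 UMIs and 4.16% mitochondrial UMIs (cluster 6 10867 and 1.31%), held 13.6% of the class in blood, 7.06% in marrow and 3.55% in spleen. Of dissociation stress genes, 1 of 13 measured members rose and 6 fell (1 and 6 adjusted over the list alone), with Fos (-1.58 ± 0.17) and Ier2 (-0.75 ± 0.12) lower. Lower too were Cebpd (-0.66 ± 0.12), Hk2 (-0.91 ± 0.17), Insyn2b (-1.61 ± 0.16), Hist1h4c (-1.86 ± 0.17) and AY036118 (-1.47 ± 0.16). The neutrophil granule genes Camp (7.70 ± 1.29), Ngp (7.25 ± 1.38) and Ltf (6.88 ± 1.5) were higher and the hemoglobin gene Hbb-bs (-2.87 ± 0.61) lower. Igkc had 3 blood UMIs and a ratio of 6509 (95% counting interval 2227 to 31565). These mark other cells. With means of per-cell counts Camp was at 2.81 and Ngp at 2.44, and Ltf was at 1.54 and not called (limma adjusted p = 0.228; over all alternatives 9.06e-07 to 0.228). In marrow monocyte-like cells, of cell cycle genes 10 of 11 measured members rose (10 adjusted over the list alone), with Ccnb2 (4.92 ± 0.40), Birc5 (4.80 ± 0.67) and Stmn1 (3.94 ± 0.56). The neutrophil granule genes Camp (10.31 ± 1.29), Ngp (9.81 ± 1.36), Ltf (9.37 ± 1.34) and Elane (4.24 ± 0.44), again markers of other cells, were higher. Under 3 other clusterings 66 to 68 of the 496 marrow cells of the class fell in immature neutrophil-like clusters. Nonclassical cluster 9 scored 1.99 for the immature neutrophil list and 1.49 for its own. Without that cluster the marrow log2 values were 6.50 for Camp, 6.41 for Ngp, 5.40 for Ltf, 4.09 for Elane, 4.92 for Ccnb2 and 5.11 for Birc5, and in spleen 3.37 for Camp, 3.12 for Ngp and 2.24 for Ltf. Of stress genes, 0 of 13 measured members rose and 7 fell (1 and 10 adjusted over the list alone), with a median of -1.36 and Dusp1 (-3.63 ± 0.54) and Fos (-2.39 ± 0.20). Lower as well were Il1b (-3.84 ± 0.55), Hes1 (-3.33 ± 0.45), Socs3 (-2.29 ± 0.30), Mcl1 (-0.71 ± 0.09), Tgfb1 (-0.79 ± 0.10) and Cd14 (-1.19 ± 0.23).

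In spleen 897 genes were higher and 363 lower (edgeR, n = 8 against 8; highest adjusted p of named genes 0.0207). With the block they numbered 1348 and 629. Of called genes 71.2% were higher, 49% with TMM and 46% with DESeq2. They numbered 51 and 117 with means of per-cell counts and 48 and 52 with thinning. In marrow 312 were higher and 412 lower (highest edgeR adjusted p 0.000629), and 491 and 626 with the block. There the counts were 161 and 392 with means of per-cell counts and 57 and 139 with thinning. Camera called 4 lists in spleen and 13 in marrow, of 21 each. With an estimated correlation, spleen lost hypoxia and glycolysis (0.207) and B cell (0.131) by camera adjusted p. Marrow lost gelatinase granule and mature neutrophil (0.368), interferon response (0.514), inflammatory cytokine and chemokine (0.334), antigen presentation (0.352) and G-CSF and NAD (0.0884) by camera adjusted p. The block added in spleen gelatinase granule and mature neutrophil (0.197 without and 0.0423 with the block) and antigen presentation (0.197 without and 0.0423 with the block), by camera adjusted p. Without spleen hashtag 4 the spleen log2 values were 6.47 for Camp, 6.17 for Ngp and 5.97 for Ltf. Igkc was at a fitted 11.58 with all sums, 9.95 without spleen hashtag 6 and 12.41 without blood hashtag 7. Hbb-bs was at -5.20 without spleen hashtag 6 and -1.95 without blood hashtag 2. With means of per-cell counts calls were lost by Ciita (1.01), Cd274 (0.69), Icam1 (0.45) and Itga4 (0.26), with limma adjusted p of 0.051, 0.187, 0.508 and 0.59. With thinning they were lost, edgeR adjusted p in parentheses, by Hk2 (0.0899), Icam1 (0.288) and Itga4 (0.183) in spleen and Tgfb1 (0.107) in marrow. Itga4 lost its call with TMM factors (edgeR adjusted p = 0.0522) and Cd274 without the nonclassical cluster (0.0771). Over all alternatives adjusted p ran for Itga4 from 0.000418 to 0.59, Cd274 from 0.00028 to 0.187, Ciita from 2.06e-06 to 0.051, Icam1 from 0.00075 to 0.508 and Hk2 from 3.05e-06 to 0.0899 in spleen and Tgfb1 from 3.89e-17 to 0.107 in marrow. Signs differed in spleen for tumor-associated neutrophil and suppressive, trafficking, matrix and angiogenesis, lipid and iron handling, unfolded protein and stress and G-CSF and NAD, and in marrow for stem and progenitor.

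Progenitor-like cells were compared between spleen and marrow, the tissues with enough of them. Higher in spleen were Slc25a21 (5.79 ± 0.65) and Scin (4.64 ± 0.46), the erythroid genes Car1 (3.37 ± 0.31), Gata1 (2.17 ± 0.40) and Klf1 (2.19 ± 0.53) and the transcription factor genes Mycn (2.53 ± 0.41), Myb (0.81 ± 0.14) and Sox4 (1.2 ± 0.28). The integrin gene Itga4 (1.41 ± 0.10) and the light chain gene Igkc (3.34 ± 0.35) were higher too. The granule enzyme genes Ctsg (-1.39 ± 0.20), Mpo (-1.04 ± 0.22) and Prtn3 (-0.96 ± 0.12) were lower. So were the stem cell antigen gene Cd34 (-1.89 ± 0.34), the chaperone gene Hspa5 (-0.93 ± 0.12), and Pkm (-0.84 ± 0.12) and Tyms (-0.78 ± 0.17). Of azurophil granule genes, 5 of 10 measured members fell (6 adjusted over the list alone), and of erythroid genes, 3 of 6 measured members rose (3 adjusted over the list alone). Stem-like cluster 22 held 55.8% of the spleen and 38.8% of the marrow class.

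Only 2 spleen sums could be formed, of hashtags 3 and 4, against marrow sums of hashtags 1 to 8. Cluster shares in blood, marrow and spleen parted hashtags 1 to 4 from 5 to 8, so the groups were unbalanced for that difference. EdgeR called 519 genes higher and 301 lower of 9801 (n = 2 against 8; highest adjusted p of named genes 0.0205), and 75 and 47 with the block. Without spleen hashtag 3 the counts were 145 and 63, with 5 lists called. Without spleen hashtag 4 there were 238 higher genes and 5 lists. With means of per-cell counts there were 1281 and 1118, and with thinning 16 and 11. Thinning ended, edgeR adjusted p in parentheses, the calls of Hspa5 (0.3), Itga4 (0.221), Tyms (0.74), Pkm (0.197), Myb (0.211), Mpo (0.237), Sox4 (0.0831) and Ctsg (0.243). Of called genes 63.3% were higher, and 52.2% with TMM. Without spleen hashtag 3 edgeR lost, adjusted p in parentheses, Cd34 (0.0735), Klf1 (0.333), Mpo (0.154), Sox4 (0.345), Gata1 (0.068) and Tyms (0.107). Without spleen hashtag 4 edgeR lost Tyms (0.0805), and with the block Tyms (0.182), Klf1 (0.0937) and Mycn (0.0721), adjusted p in parentheses. Slc25a21 lost its call with DESeq2 (adjusted p = 0.156). Over all alternatives adjusted p ran for Cd34 from 7.46e-06 to 0.0735, Klf1 from 0.00116 to 0.333, Mpo from 3.97e-05 to 0.237, Sox4 from 0.00215 to 0.345, Gata1 from 8.84e-06 to 0.068, Tyms from 0.00169 to 0.74, Mycn from 2.17e-06 to 0.0721, Slc25a21 from 9.35e-08 to 0.156, Hspa5 from 2.81e-09 to 0.3, Itga4 from 6.43e-26 to 0.221, Pkm from 4.72e-08 to 0.197, Myb from 7.38e-05 to 0.211 and Ctsg from 6.44e-10 to 0.243. Car1 was at 2.76 without spleen hashtag 3 and Cd34 at -2.51 without 4. Without marrow hashtag 3 Scin was at 5.23 and Slc25a21 at 6.43, and without marrow hashtag 4 Slc25a21 was at 6.40. Camera called 8 of 21 lists and lost all with an estimated correlation, adjusted p in parentheses: azurophil granule (0.441), specific granule (0.543), cell cycle (0.441), hypoxia and glycolysis (0.12), matrix and angiogenesis (0.221), oxidative burst and NET (0.441), antigen presentation (0.543) and erythroid (0.441). The block added gelatinase granule and mature neutrophil (0.28 without and 0.0105 with the block), by camera adjusted p. Signs differed for lipid and iron handling and B cell.

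Surface antibodies, compared after seeing the data, gave protein values on the same cells. On tumor neutrophil-like cells (n = 4) against blood (n = 8), the homing receptor CD62L and the chemokine receptor CXCR2 were lower, by centred log2 differences of -6.58 and -3.69. Lower too were CD44 (-2.71) and CD11a (-1.85), and higher CD64 (4.25), CD14 (3.64), MHCII (2.44), CXCR4 (1.51) and CD11b (1.05). Each lay beyond all blood sums in 4 of 4 tumor sums, with an exact permutation p of 0.00404, the smallest possible, and an adjusted p of 0.00715. That test exchanges sums freely. Within the 4 pairs of equal hashtag number the smallest exact permutation p is 0.125, which 16 of 18 antibodies reached, so the paired design cannot call any on these cells (lowest adjusted p = 0.148). CD24 differed by 0.47 and was not called (exact permutation adjusted p = 0.289), but without centring it was at 1.12 and called (adjusted p = 0.0253). The labels describe digestion for the tumor alone. Its effect on surface antibodies was not tested, so for tumor cells of either class it cannot be told apart from the tissue. On marrow neutrophil-like cells CD106 (3.41), MHCII (2.12) and ckit (1.34) were higher and CXCR2 (-2.14), CD11a (-1.53) and CD11b (-1.51) lower. On spleen neutrophil-like cells MHCII (2.59) and CD106 (1.2) were higher and CXCR2 (-0.77) and CD11a (-0.80) lower. Each of these held in 8 of 8 sums, with an exact permutation p of 0.000155, the smallest possible, and an adjusted p of 0.000883. Immature shares differed, as given above, and antibodies were not compared within mature clusters alone, so maturity and tissue cannot be told apart here. CXCR4 differed by 0.17 in marrow and was not called (exact permutation adjusted p = 0.227), but without centring it was at 1.06 and called (adjusted p = 0.0024). MHC class II genes led dendritic-like cluster 11, and whether dendritic-like cells gave MHCII signal was not tested.

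On tumor monocyte-like or macrophage-like cells (n = 5) CD115 (-4.87) and CD62L (-5.67) were lower and CD64 (3.89), CD14 (2.97), MHCII (2.68) and CXCR4 (1.95) higher than in blood. On marrow cells of the class CD106 (2.45) was higher and CXCR2 (-1.68) lower, and on those of spleen CD106 (1.56) and MHCII (1.56) were higher. Of 18 antibodies, 9 were higher and 7 lower in tumor for each class. For neutrophil-like cells 5 were higher and 9 lower in marrow, and 4 and 7 in spleen. For monocyte-like cells the counts were 4 and 5 in marrow, and 5 and 7 in spleen. Without centring, 12 were higher and 3 lower on marrow neutrophil-like cells, and 9 and 3 on those of spleen. On spleen monocyte-like cells they were then 8 and 1, so directions hold relative to the mean antibody. Within pairs of equal hashtag number no antibody could be called on tumor monocyte-like or macrophage-like cells (5 pairs, smallest exact permutation p = 0.0625, reached by 16), and on those of spleen 4 were lower in place of 7. With a stricter hashtag margin 2 tumor neutrophil-like sums were left and 0 antibodies were called (exact permutation test, lowest adjusted p = 0.0623), while 16 had an unadjusted p of 0.0444, the smallest possible.

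**Figure D4:**
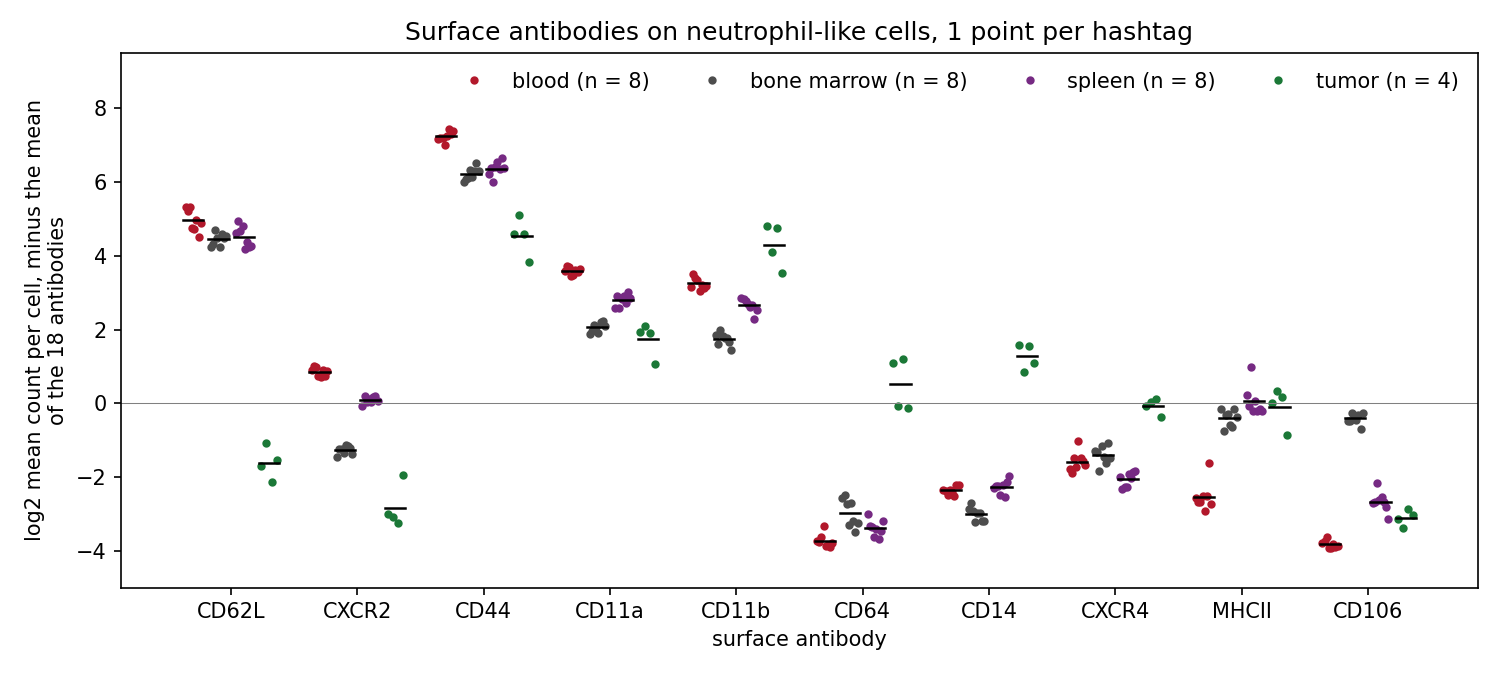
Surface antibodies (horizontal) on neutrophil-like cells, as log2 mean count per cell minus the mean of the 18 antibodies (vertical), 1 point per hashtag sum; black lines are means. CD62L lies at -1.61 in tumor and 4.96 in blood.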

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

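The tests of many hashtags on a cell, of immature cells and of handling as explanations, and the differences between classes, were chosen only after the results were seen.

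Values far from the others of their group were found in 16 of 291 groups of hashtag values, where chance gives about 1 in 20. Progenitor-like cells were 5.58 (others 0.972 to 3.12), in %, of spleen cells for hashtag 4. In tumor neutrophil-like sums the CPM of Cd80 was 686 (others 1246 to 1312) for hashtag 7, and hashtag 4 had 0 (others 51.7 to 85.8) for Slc40a1 and 0 (others 103 to 189.8) for Pf4. In blood neutrophil-like sums hashtag 1 had 196 (others 2.88 to 21.4) CPM of Camp. Hashtag 8 had 1678 (others 1872 to 1977) CPM of Mcl1 and 43.8 (others 74.1 to 109) of Atf3, and 43.9 (others 74.1 to 109.7) of Atf3 in mature clusters. In spleen neutrophil-like sums H2-Ab1 was at 48.5 (others 18.5 to 25.7) CPM for hashtag 3, Defb37 at 3.23 (others 7.83 to 14.9) for hashtag 7 and Fth1 at 3084 (others 4115 to 5259.8) for hashtag 4. Stmn1 was at 185 (others 240.3 to 271) CPM in the marrow neutrophil-like sum of hashtag 7. In blood monocyte-like sums Clec2g was at 114 (others 51.3 to 74.5) CPM for hashtag 7, Ciita at 50.7 (others 11.3 to 21.1) for hashtag 1 and Hbb-bs at 266 (others 27.3 to 53.7) for hashtag 2. The marrow monocyte-like sum of hashtag 4 had 0 (others 6.8 to 18.2) CPM of Il1b.

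The difference between marrow and blood was not the same in both classes for 3 lists, over 6 two-sided exact permutation tests of that difference of list means. The dissociation stress list changed by -2.48 in neutrophil-like and -1.27 in monocyte-like cells. The difference of -1.21 lay below all blood values in 8 of 8 sums (exact permutation p = 0.000155, the smallest possible; adjusted p = 0.000932). The inflammatory list differed by -0.76 (7 of 8 sums; exact permutation adjusted p = 0.000932) and the interferon list by -0.66 (4 of 8 sums; exact permutation adjusted p = 0.0261). Within pairs of equal hashtag number the interferon call was lost (exact permutation adjusted p = 0.0625) and the other 2 held (0.0234 each). In spleen the same tests gave differences of 0.026, -0.13 and -0.35 for interferon, stress and inflammatory lists (exact permutation adjusted p = 0.883, 0.413 and 0.186), none called. Hashtags 9 and 10, used in no comparison, had 9 and 591 counts over all cells, above the limit that a count of 0 allows.

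Genes of the tumor neutrophil-like cells far above blood could come from RNA of tumor macrophages, from the digestion of the tissue or from the tumor itself. If macrophage RNA were the source, macrophage markers would be at least as high in these cells, relative to macrophage-like cells, as the 12 genes with the largest changes. The median ratio was 2.48 for those genes and 0.0659 for the markers, 37.7 times apart (32.9, 14 and 35.7 for hashtags 3, 4 and 6, and markers at 0 for hashtag 7), which argues against that source for these genes as a set. The median of the dissociation stress list was 1.81, as digestion would give, so digestion stays open. An effect of the tumor itself stays open as untested, since the labels describe digestion for the tumor alone.

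Several hashtags were found on 47.7% of cells of nonclassical monocyte-like cluster 9, 67.9% of tumor macrophage-like cluster 26 and 43.3% of neutrophil-like cluster 20. The 10 clusters with most such cells, 9, 18, 26, 7, 1, 10, 22, 4, 6 and 20, held 281 down to 68. Doublets of cells from different mice would hold more RNA, and cells with several hashtags had 1.58 and 1.93 times the median UMIs of cells with 1 in clusters 9 and 26 (1.37 in cluster 20), so doublets stay open. Binding of tags to cells that already carry their own would raise other antibodies too, and these were 2.9 and 3.12 times as high. S100a8 and S100a9 together, which neutrophil doublets would bring, were 1.69 and 1.34 times as high, on both sides of the bound set for binding. Cluster 9 cells with 1 hashtag already held 47639 CPM (1250 in cluster 6). So in these 2 clusters binding cannot be told apart from doublets. In clusters 6, 10, 11, 12, 22 and 25 the ratio was 6.73 to 15.8, as neutrophil doublets would give. No biological explanation was tested.

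Immediate early genes were lower in marrow than in blood neutrophil-like cells. If immature marrow cells were the cause, the difference would end among cells of like maturity. In mature clusters the median of the stress list was -2.07, but 12 of 12 specific granule genes still rose there (median 2.82), so maturity was not level and immature cells stay open. Handling of the tissues before capture would act on every cell, and the median in monocyte-like cells was -1.36, so handling stays open. The larger fall in neutrophil-like cells, given above, cannot weigh on this, as 52.9% of these were immature in marrow. A difference between the tissues themselves is confounded with the library and stays open as untested.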

How the results depend on the processing

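All alternatives for mature clusters, erythroid-like cells and surface antibodies, and for the other comparisons mature clusters only, 20 cells per tumor sum and the nonclassical cluster left out, were chosen after seeing the data. For monocyte-like or macrophage-like and progenitor-like cells so were DESeq2, leaving out each sum, the block, the stricter margin and the cell minima; all other alternatives were chosen before the data were examined.

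Of 4760 values of the 184 named genes under alternatives, 4707 had the main direction and call, 51 lost the call and 2 turned around. The reversed ones were Chil3 at -0.69 and Cebpe at -0.10 in mature clusters of spleen. Of 194 antibody values 167 were the same, 24 lost and 2 gained a call (without centring, CXCR4 on marrow and CD24 on tumor neutrophil-like cells), and CXCR4 on marrow neutrophil-like cells turned to -0.045 with a pseudocount of 0.1. Most of these lost calls came with the block (19), thinning (16), the stricter margin (11), means of per-cell counts (8) and progenitor-like cells without spleen hashtag 3 (6). The lost calls of genes stand beside the comparisons. Fold changes of named genes moved by over 1.5 times for 111 of 184 values with means of per-cell counts, 51 of 134 with thinning, 29 of 79 in mature clusters, 28 of 184 with DESeq2, 22 of 129 with Leiden resolution 0.5 and 20 of 178 with the stricter margin.

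Counts that moved by over 1.5 times are given by setting. Thinning to 1000 UMIs, which leaves out shallower cells and most counts, gave 406 higher and 397 lower genes in neutrophil-like cells of tumor, 650 higher and 327 lower genes with 5 lists in neutrophil-like cells of spleen, 1053 higher and 2886 lower genes in neutrophil-like cells of marrow, 444 higher and 1637 lower genes in mature clusters of marrow, 325 higher and 295 lower genes in monocyte-like or macrophage-like cells of tumor, 48 higher and 52 lower genes with 1 list in monocyte-like cells of spleen, 57 higher and 139 lower genes with 7 lists in monocyte-like cells of marrow, 16 higher and 11 lower genes with 2 lists in progenitor-like cells and 13 higher and 10 lower genes with 1 list in erythroid-like cells. Means of per-cell counts gave 5722 lower genes in neutrophil-like cells of tumor, 185 higher and 322 lower genes in neutrophil-like cells of spleen, 1792 higher and 2502 lower genes in neutrophil-like cells of marrow, 354 higher and 1318 lower genes in mature clusters of marrow, 51 higher and 117 lower genes in monocyte-like cells of spleen, 161 higher genes in monocyte-like cells of marrow, 1281 higher and 1118 lower genes in progenitor-like cells and 168 higher and 349 lower genes in erythroid-like cells. The filter at 500 summed UMIs, which tests fewer genes, gave 1651 higher genes in neutrophil-like cells of spleen, 1939 higher genes in neutrophil-like cells of marrow, 2 lists in monocyte-like cells of spleen, 4 lists in progenitor-like cells and 253 higher and 313 lower genes with 6 lists in erythroid-like cells, and no filter gave 1209 lower genes in erythroid-like cells. The stricter margin, which leaves fewer cells, gave 538 higher and 541 lower genes in neutrophil-like cells of tumor and 1265 higher and 1049 lower genes in monocyte-like or macrophage-like cells of tumor, and 0 higher and 0 lower antibodies on tumor neutrophil-like cells. Mature clusters alone gave 1005 higher and 604 lower genes in neutrophil-like cells of spleen and 830 higher genes in neutrophil-like cells of marrow. DESeq2 gave 5840 higher and 2191 lower genes in neutrophil-like cells of marrow, 1865 higher and 1576 lower genes in mature clusters of marrow and 727 lower genes in monocyte-like cells of spleen, and TMM factors 1501 higher and 1871 lower genes in mature clusters of marrow and 546 higher and 569 lower genes in monocyte-like cells of spleen. Leiden resolution 0.5 gave 9 lists in mature clusters of marrow and 1260 higher and 2135 lower genes in erythroid-like cells. With 20 cells per tumor sum and with 50 cells per sum there were 9 lists in mature clusters of marrow. The hashtag number as a block gave 1348 higher and 629 lower genes in monocyte-like cells of spleen, 491 higher and 626 lower genes in monocyte-like cells of marrow and 75 higher and 47 lower genes in progenitor-like cells. For antibodies it gave 0 higher and 0 lower on tumor neutrophil-like and on tumor monocyte-like or macrophage-like cells, where so few pairs cannot pass the threshold, and 4 lower on spleen monocyte-like cells. It changed no other count by as much, and its lost or added calls of genes and lists stand beside the comparisons. Antibody values without centring gave 12 higher and 3 lower on marrow neutrophil-like, 9 and 3 on spleen neutrophil-like and 8 and 1 on spleen monocyte-like cells. Beyond what the wording of a setting states, the cause was not tested.

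Leaving out each sum in turn gave 685 to 956 higher genes, 815 to 1515 lower genes and 13 to 14 lists in neutrophil-like cells of tumor; 2214 to 2510 higher genes, 1161 to 1320 lower genes and 8 to 10 lists in neutrophil-like cells of spleen; 3062 to 3272 higher genes, 4308 to 4535 lower genes and 14 to 16 lists in neutrophil-like cells of marrow; 758 to 822 higher genes, 2978 to 3524 lower genes and 14 to 15 lists in mature clusters of marrow; 1670 to 1947 higher genes, 1598 to 2079 lower genes and 11 to 14 lists in monocyte-like or macrophage-like cells of tumor; 675 to 945 higher genes, 283 to 379 lower genes and 4 to 5 lists in monocyte-like cells of spleen; 223 to 308 higher genes, 304 to 419 lower genes and 11 to 14 lists in monocyte-like cells of marrow; 145 to 609 higher genes, 63 to 377 lower genes and 5 to 9 lists in progenitor-like cells; 279 to 454 higher genes, 446 to 795 lower genes and 8 to 10 lists in erythroid-like cells. Antibody counts in tumor were 8 to 9 higher and 6 to 7 lower on neutrophil-like and 8 to 9 higher and 7 to 7 lower on monocyte-like or macrophage-like cells, each tumor sum left out in turn. Leaving out 1 sum moved counts by over 1.5 times: tumor hashtag 6 (neutrophil-like), spleen hashtags 3 and 4 (progenitor-like) and marrow hashtag 3 (erythroid-like). The counts stand beside the comparisons. Each of the progenitor-like fits leaves 1 spleen sum, assumed to vary like the marrow sums.

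Shares of cells moved with the clustering, in percent. Without low-quality cells, neutrophil-like shares were 58.6 in blood and 46.5 in spleen and monocyte-like shares were 7.44 in marrow and 63.8 in tumor. With Leiden resolution 0.5, monocyte-like shares were 11.6 in blood, 6.88 in marrow, 14.3 in spleen and 71.6 in tumor, progenitor-like shares were 10.3 in marrow and 0.753 in spleen and the neutrophil-like share was 0.433 in tumor. With 15 principal components, monocyte-like shares were 14.2 in marrow and 17 in spleen and progenitor-like shares were 14.6 in marrow and 3.1 in spleen. Without the 8 cells Scrublet marked, progenitor-like shares were 10.6 in marrow and 0.852 in spleen. With cell cycle, ribosomal and mitochondrial genes left out, monocyte-like shares were 10.3 in marrow and 68.2 in tumor, progenitor-like shares were 9.12 in marrow and 0.803 in spleen and the neutrophil-like share was 1.3 in tumor. Some of these moves follow from the naming and merging of clusters. Without low-quality cells, cluster 3 took 1924 blood, 172 marrow and 1060 spleen neutrophil-like cells and was named erythroid-like, though its best list was mature neutrophil (score 1.83 against 1.79). Tumor neutrophil-like cells joined macrophage-like clusters with Leiden resolution 0.5 (101 of 107) and with cell cycle, ribosomal and mitochondrial genes left out (100). Progenitor-like marrow cells went to an unnamed cluster in the latter (386 of 1021) and without Scrublet's cells (388), to an erythroid-like one with Leiden resolution 0.5 (438) and to a monocyte-like one with 15 principal components (231). Marrow monocyte-like cells went to neutrophil-like clusters without low-quality cells (66) and with Leiden resolution 0.5 (68, and 35 to a plasma-like one), and 88 progenitor-like and 71 B- or plasma-like cells joined them with cell cycle, ribosomal and mitochondrial genes left out. Each other moved share also came with at least 20 cells that changed class, and why they clustered differently was not tested. No value could be had with Leiden resolution 0.5 for tumor neutrophil-like and progenitor-like cells, with 50 cells per sum for tumor, progenitor-like and erythroid-like cells, and with 20 cells per tumor sum for tumor monocyte-like or macrophage-like cells. Alternatives for a genotype comparison and for clusters of pooled tissues were not run, since neither comparison was made. Depth limits the tumor neutrophil-like sums most, at 11656 to 121166 UMIs.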

Other observations

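The comparison of erythroid-like cells, all splits of the samples and the look at clusters per hashtag were chosen only after seeing the data.

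Erythroid-like cells of spleen (n = 5 sums) were compared with those of marrow (n = 5). The spleen sums were of hashtags 1, 2, 3, 4 and 6 and the marrow sums of 3, 4, 5, 6 and 8, so the groups were unbalanced for the difference in cluster shares between hashtags 1 to 4 and 5 to 8. With the hashtag number as a block edgeR called 378 genes higher and 789 lower. Cluster 25 held all 253 marrow and 211 of 216 spleen cells of the class. It scored 0.968 for the erythroid list, with 1 marker of that class among its 10 leading genes. Under other clusterings, erythroid-like clusters of mainly marrow and spleen cells scored 0.576 to 0.879 for that list. They scored higher, 1.53 to 2.04, for the granulocyte-monocyte progenitor and promyelocyte list, so the name of the class is uncertain. The red cell genes Ermap (0.81 ± 0.12) and Car1 (0.69 ± 0.12) and the hemoglobin gene Hbb-bs (8.73 ± 1.81) were higher in spleen, as were Hes1 (5.95 ± 0.34), Cd74 (4.49 ± 0.84) and Sh3tc2 (4.45 ± 0.34) and the apoptosis gene Bcl2l11 (2.01 ± 0.26). The granule genes Mpo (-6.13 ± 0.65), Ctsg (-7.68 ± 0.65) and Camp (-3.63 ± 0.19), the platelet gene Pf4 (-8.59 ± 1.49) and the stem cell transcription factor genes Gata2 (-1.71 ± 0.20) and Mecom (-3.83 ± 0.48) were lower. Elane had 1 spleen UMI and lay at 0.0052 (95% counting interval 0.000131 to 0.0294) of its marrow level. Of erythroid genes, 7 of 12 measured members rose and 0 fell (10 and 1 adjusted over the list alone). Of azurophil granule genes 9 of 10, of specific granule genes 7 of 7 and of platelet genes 3 of 3 measured members fell. Adjusted over the list alone, the counts were equal. Of stem and progenitor genes, 1 of 10 measured members rose and 7 fell (1 and 8 adjusted over the list alone).

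EdgeR called 422 of 7880 genes higher and 669 lower in spleen. Means of per-cell counts gave 168 and 349, and thinning 13 and 10. Classes from Leiden resolution 0.5 gave 1260 and 2135. The highest edgeR adjusted p of the 14 named genes was 0.00352. Camera called 10 of 18 lists, and azurophil granule, specific granule and platelet held with an estimated correlation. Those calls were lost with an estimated correlation and the block (camera adjusted p = 0.162, 0.162 and 0.235). Without bone marrow hashtag 3 there were 279 higher genes and Hbb-bs was at 9.35, and it was at 6.61 without spleen hashtag 2. Pf4 was at -7.27 without bone marrow hashtag 8 and -9.19 without spleen hashtag 4, and Mecom at -5.19 without spleen hashtag 1. Without spleen hashtag 1 the values were -9.63 for Mpo and -8.81 for Ctsg, and without spleen hashtag 6 3.69 for Cd74 and -8.18 for Elane (-6.90 with all sums). With Leiden resolution 0.5 Camp was at -0.45 and not called (edgeR adjusted p = 0.744; over all alternatives 6.52e-51 to 0.744). Signs of median, mean or test differed for trafficking and antigen presentation.

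Hashtags differed in which clusters their cells fell into. Cluster 4, led by the interferon-inducible genes Rsad2, Slfn4, Isg15 and Oasl2, held 42.6, 25.8, 30.2, 28.3, 0.138, 0.295, 0.233 and 0% of the blood neutrophil-like cells of hashtags 1 to 8 in turn. In marrow the shares were 5.44, 3.58, 3.99, 1.31, 0, 0, 0 and 0%, and in spleen 35.6, 22, 23.4, 25, 0, 0, 0 and 0.214%. Monocyte-like cluster 6, led by Fn1, S100a4 and Ighg2c, held 10.3, 6.94, 10, 3.53, 70.7, 73.5, 71.4 and 73.9% of the monocyte-like or macrophage-like cells in blood, 0, 10, 18.5, 11.1, 94, 86.2, 71.9 and 93.2% in marrow and 6.82, 3.75, 7.91, 11.8, 80.8, 78.9, 84.1 and 84.8% in spleen. Monocyte-like cluster 10, led by Ifi27l2a, Ms4a4c and Ifitm3, held 43.6, 63.9, 50, 74.1, 0.752, 0, 1.3 and 0%, 71.4, 71.7, 58.9, 71.1, 0, 0, 0 and 0% and 65.9, 61.2, 56.8, 60.8, 3.85, 0, 0 and 0%. These values fell into 2 separate clusters in blood, marrow and spleen, with hashtags 1 to 4 on one side and 5 to 8 on the other. The labels tie no hashtag to a mouse or genotype, so no test was made. The correlations between sums of the same hashtag number contain this difference.

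The sums of each comparison with at least 3 per group were split in other ways, 100 splits each with the real one among them, and the genes called were counted. In each of the 8 comparisons only 1 split, the real one, called as many. Since the numbers pair the sums, chance is weighed among the splits that part all pairs of equal hashtag number as the real one does. Those of tumor neutrophil-like cells are too few for a share under 0.05. For the other 7 comparisons the share of the real split was under 0.05. These shares were not adjusted over the 8 comparisons and rest on few splits, so they argue against chance without excluding it. Real count against the highest of the other splits was 2421 against 478 for tumor, 3800 against 2809 for spleen and 7801 against 6187 for marrow neutrophil-like cells, and 4175 against 2608 for mature clusters. It was 4024 against 2918 for tumor monocyte-like or macrophage-like cells, 1260 against 252 for spleen and 724 against 202 for marrow monocyte-like cells, and 1091 against 249 for erythroid-like cells. In the same order, 16, 52, 52, 52, 32, 52, 52 and 22 of the 100 splits parted all pairs. The highest other counts were 453, 2809, 6187, 2608, 2230, 208, 163 and 249 among these and 478, 2294, 5972, 1813, 2918, 252, 202 and 2 among the rest. Some other splits of neutrophil-like and tumor sums also had high counts. Splits that exchange few sums keep most of the tissue difference. How many sums each split shared with the real one was not recorded, so the reason for these counts was not tested. How splits were drawn was changed once after a first random draw.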
